A study of Homo sapiens with 7 samples.

How the data were processed

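RNA was measured by sequencing in 7 libraries of T47D, an estrogen receptor-positive human breast cancer cell line. Per the labels, 3 libraries came from parental cells and 2 each from resistant clone 4 and resistant clone 2, and the labels number the libraries of each group as biological replicates from 1. The names of the clone 2 libraries called replicates 1 and 2 carry 4 and 6 instead. Resistant cells had been grown for 6 months in palbociclib, an inhibitor of CDK4 and CDK6, rising from 1 uM to 5 uM, per the labels' protocols. The same protocols state that experiments were done without the drug in the medium unless noted otherwise. The libraries were therefore taken to compare resistant with sensitive lines and not treated with untreated cells. Lasting effects of the earlier drug exposure cannot be told apart from resistance in this design. Nothing in the labels says how the replicate cultures of a clone were kept apart, or whether they were separate. The p-values therefore measure the spread between these libraries, estimated over all groups, and say nothing about other clones.

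The authors deposited a table of raw read counts per Ensembl gene, with gene names, and these whole-number counts were used as they stood. The submitters' processing notes name FastQC, CASAVA and STAR, without versions, and the hg19 build. The counting program, the annotation release and the strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping genes cannot be told apart, and reads of near-identical gene copies, such as the MAGEA family, may be split by the counting. The table held 63677 genes, of which 6724 had no gene name, and these took 1.02% to 1.41% of the counts per library. All 7 columns of values matched a labelled library.

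Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with enough counts for their group (filterByExpr, minimum count 10) were kept, leaving 17502, and libraries were scaled by TMM. A quasi-likelihood model with 3 group means was fitted to all 7 libraries with robust estimation of the spread, so that the groups of 2 shared an estimate with the others. The contrasts were clone 4 against parental, clone 2 against parental, the mean of both clones against parental, and clone 2 against clone 4. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Standard errors of log2 fold changes were taken from the quasi-F statistic, and levels are TMM-scaled CPM (edgeR) unless stated otherwise. The common biological coefficient of variation was 0.0997. Where a group had 0 counts of a gene, its fold is a lower bound set against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of counts is given with its exact 95% interval. Intervals and floors cover counting error only.

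In total, 33 gene lists for cell cycle, DNA repair, signalling, metabolism and cell type were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. The 32 lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over lists. Camera with an estimated correlation and the self-contained test fry were alternatives. Counts of called list members are given over all genes tested and adjusted over the list alone. They are to be read beside the shares called among all genes tested. These were 44.4% in clone 4 and 42.5% in clone 2 against parental, and 36.5% between the clones, about equally in both directions.

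Named genes had a mean of at least 2 log2 CPM and a symbol outside the LOC, MIR, SNOR, RNU and clone-based RP families. They were the 8 highest and 8 lowest genes called in both clones by the smaller fold. They also included the 4 highest and 4 lowest per clone among genes called in that clone alone and between the clones, and the 6 highest and 6 lowest between the clones. Up to 4 called members of each described list were added without the level minimum. A set of cell cycle, hormone receptor, STAT3 and DNA repair genes was named whatever its values. Near-identical copies are named once.

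The alternatives were RLE scaling, DESeq2 1.42.0, no filter beyond 1 count, a stricter filter (1 CPM in a group and 50 counts in all), a test against a fold of 1.5, fits with only the groups compared, the replicate number as a block, and leaving out each library. In simulated counts with known changes, 67 of 16967 genes tested were changed 1.5-fold, 67 2-fold and 66 4-fold in clone 4. The clone 4 contrast recovered 50.7%, 74.6% and 98.5% of them. With as many genes changed, the shares were 50.7%, 83.6% and 98.5% for clone 2 among 16994 genes tested. They were 40.3%, 73.1% and 95.5% between the clones among 16970. Far fewer genes were changed than were called in the data, so the adjusted cutoff was stricter in the simulations. These shares therefore do not give the power in the data. Gene order, chromosome, GC content and transcript length came from GENCODE 29, which 96.8% of the tested genes matched by Ensembl identifier. That annotation is of another build than the authors used, so no coordinates are given. Gene order was analysed in Python 3.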

Results

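The data are gene-level read counts of 7 T47D libraries. Parental cells, sensitive to palbociclib, gave 3 libraries of 12436758 to 17524621 counts. Resistant clone 4 gave 2 libraries of 12593774 and 14739350 counts, and resistant clone 2 gave 2 of 10997625 and 15677914. Libraries of a group correlated at 0.987 to 0.994 across genes on the log2 scale, and libraries of different groups at 0.934 to 0.963. The clone 2 libraries lay closest, with a chi-square of 1.49 per degree of freedom, still above sampling noise, against 13.3 for clone 4 and 5.49 to 17.5 for parental pairs. The labels call them biological replicates but do not say that they were separate cultures, so their spread, and p-values resting on it, may be technical. The series title places the work in palbociclib-resistant, estrogen receptor-positive breast cancer, with STAT3 and DNA repair as its subject.

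The comparison of clone 4 with parental cells asks what separates this resistant line from its origin. RB1, whose protein holds back the cell cycle until CDK4 and CDK6 inactivate it, fell from 55.2 ± 4.8 CPM (SD, n = 3) to 0.194 ± 0.080 CPM (SD, n = 2). Its log2 fold change was -8.13 (SE 0.25, edgeR adjusted p = 3.6e-11). CCNE1, the cyclin that activates CDK2, rose by a log2 fold change of 1.21 (SE 0.17), CDK6 by 1.11 (SE 0.22), E2F1 by 0.76 (SE 0.11) and the CDK inhibitor CDKN1A by 0.86 (SE 0.10). RBL2, a relative of RB1, fell by 1.21 on the log2 scale (SE 0.11). CDK4, CDK2 and CCND1 had log2 fold changes of -0.15, -0.20 and -0.01 and were not called. Without parental replicate 3, CDK4 was called lower (-0.23, edgeR adjusted p = 0.0483). CCNE2, at 0.39 (adjusted p = 0.035), lost its call in 6 of the 7 fits without a library, with adjusted p between 0.0587 and 0.171 in those. As a list, the CDK4/6-RB axis had 8 of 22 measured members higher and 3 lower, the same counts adjusted over the list alone, and was not called (camera adjusted p = 0.805). Camera tests for a shared direction, and this list holds both drivers and inhibitors of the cycle. A missing call therefore does not mean, in either clone, that the axis was unchanged.

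**Figure D1:**
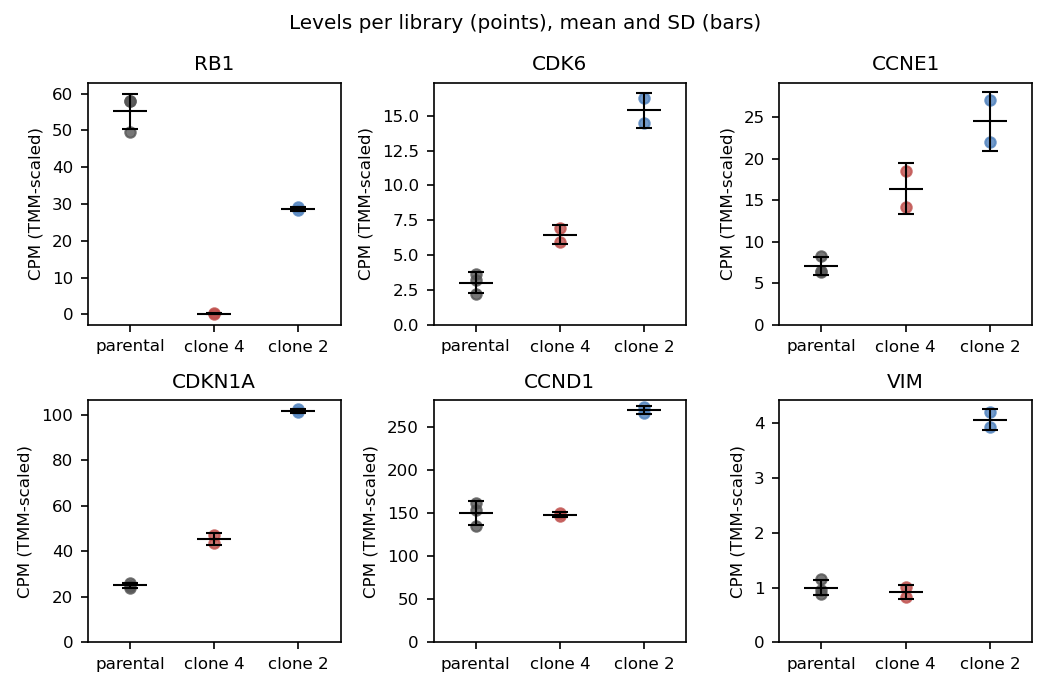
Levels of 6 genes in CPM (y axis, TMM-scaled, from 0) by group (x axis), with a point per library and bars for mean and SD (n = 3 parental, n = 2 per clone). RB1 lay at 0.194 CPM in clone 4 and 28.7 CPM in clone 2 against 55.2 CPM in parental cells, while CDK6, CCNE1 and CDKN1A were highest in clone 2.

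Interferon-stimulated and inflammatory genes rose together in clone 4. Of 41 measured members of the type I interferon list, 38 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 2.76. IFI27 went from 3.15 ± 0.96 to 417 ± 25 CPM, IFI44 rose by 8.04 (SE 0.39) and XAF1 by 6.22 (SE 0.25) on the log2 scale. The camera adjusted p was 1.36e-74, but adjusted p = 0.179 with an estimated correlation. In the NF-kB list 13 of 18 members rose and 1 fell (14 and 1 adjusted over the list alone). They included BIRC3, an inhibitor of apoptosis, at 4.01 (SE 0.15), and the chemokine CCL20 at 4.77 (SE 0.52). This call held with an estimated correlation (adjusted p = 0.0449). MHC class I antigen presentation had 12 of 17 members higher and 3 lower (13 and 3 adjusted over the list alone), among them the immunoproteasome subunit PSMB9 at 1.86 (SE 0.12), with adjusted p = 0.298 with an estimated correlation. Leukocyte transcripts stayed low beside these lists, with PTPRC, CORO1A, LAPTM5, TYROBP, CD3E and LYZ summing to 1.19 and 2.51 CPM, by library total, in the clone 4 libraries. Of the 5 tested members of the leukocyte list 2 rose and none fell: ITGAM, with 28 and 26 counts against 0, 1 and 1 in parental cells, and CD68, with 67 and 55 against 28, 29 and 25, both named after their values were seen.

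The IL-6/JAK/STAT3 list rose in clone 4, with 19 of 36 members higher and 6 lower (20 and 6 adjusted over the list alone). Its camera adjusted p was 0.00468, and adjusted p = 0.275 with an estimated correlation. SOCS3, a feedback inhibitor that STAT3 induces, rose from 2.45 ± 0.41 to 12.5 ± 0.15 CPM, and the cytokine LIF rose by a log2 fold change of 3.32 (SE 0.33). STAT3 itself was at 0.16 (SE 0.096) and not called. IL6ST rose by 0.47 (SE 0.13), a call lost without clone 4 replicate 1 (0.33, adjusted p = 0.0953). IL6 had 3 counts over both clone 4 libraries and 0 in parental cells, too few to test. IRF9 and CXCL10 of this list are also interferon-stimulated genes. CXCL10 had 32 counts in clone 4 against 1 in parental cells, a ratio of 51.4 (95% interval 8.59 to 2090).

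Sterol genes were mostly lower in clone 4, and a smaller part of the glycolytic genes was. In the cholesterol synthesis list 16 of 23 members fell and 1 rose, the same adjusted over the list alone, led by NSDHL at -1.88 (SE 0.15) and STARD4 at -1.16 (SE 0.17). The camera adjusted p was 0.00194, and adjusted p = 0.949 with an estimated correlation. The hypoxia and glycolysis list had 12 of 25 members lower and 1 higher, also over the list alone, including PGK1 at -1.10 (SE 0.13) and PKM at -0.86 (SE 0.097). Its adjusted p of 0.0251 rose to 0.0638 without parental replicate 1, 0.0539 without parental replicate 2 and 0.0594 without clone 4 replicate 2, and was 0.949 with an estimated correlation.

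DNA repair lists were not called by camera in clone 4. Homologous recombination had 3 of 30 members higher and 8 lower, also over the list alone (camera adjusted p = 0.967). BRCA2 fell from 8.48 ± 1.6 to 3.62 ± 1.1 CPM, a log2 fold change of -1.20 (SE 0.23), while BRCA1 was at 0.02 and not called. XRCC3 rose by 0.80 (SE 0.13). Nucleotide excision repair had 10 of 20 members lower and 2 higher (10 and 3 adjusted over the list alone, camera adjusted p = 0.0745, 0.0093 with no filter beyond 1 count and 0.682 with an estimated correlation), including CUL4A at -1.68 (SE 0.11) and XPA at -1.16 (SE 0.17). The estrogen receptor list went both ways, with 6 of 30 members higher and 11 lower (7 and 11 adjusted over the list alone, camera adjusted p = 0.678). ESR1 was at -0.05 and not called, PDZK1 rose by 1.65 (SE 0.21) and PGR fell by 0.83 (SE 0.21). The PGR call was lost without clone 4 replicate 2 (-0.57, adjusted p = 0.112). CDH1, which encodes E-cadherin, fell by 0.46 (SE 0.11), and VIM, which encodes vimentin, was at -0.12 and not called.

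In all, edgeR called 7771 of 17502 genes in clone 4 against parental, 3862 higher and 3909 lower, of which 1479 rose and 1204 fell at least 2-fold. A test against a fold of 1.5 called 2382. Called here and between the clones but not in clone 2 were CITED1, ARHGAP15, C4orf48 and PIP, higher by log2 fold changes of 2.81, 2.47, 2.37 and 2.14, and SCARA3, L1CAM, EYA2 and PNPLA4, lower at -4.51, -3.98, -3.11 and -2.75. PIP, a secreted protein of apocrine breast cells, reached 1910 ± 28 CPM from 431 ± 160. L1CAM was no longer called without either clone 4 library (adjusted p = 0.05 and 0.0622).

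The comparison of clone 2 with parental cells asks the same of the other line. RB1 fell to 28.7 ± 0.53 CPM (SD, n = 2), a log2 fold change of -0.94 (SE 0.12, edgeR adjusted p = 2.9e-05). CDK6, a target of palbociclib, rose from 3.03 ± 0.75 to 15.4 ± 1.3 CPM, a log2 fold change of 2.37 (SE 0.20). CDKN1A rose by 2.02 (SE 0.10), CCNE1 by 1.81 (SE 0.17) and CCND1, cyclin D1, by 0.85 (SE 0.10). CDK2, CCNE2 and E2F1 were at -0.14, -0.28 and 0.20 and not called, though CCNE2 was called without parental replicate 2 (-0.39, adjusted p = 0.0462). CDK4 fell by 0.36 (SE 0.10), a call lost without either clone 2 library (adjusted p = 0.0687 and 0.122). The CDK4/6-RB list had 8 of 22 members higher and 3 lower, also over the list alone, and was not called (camera adjusted p = 0.0651), but was called without parental replicate 3 (adjusted p = 0.0116), with adjusted p = 0.783 with an estimated correlation in the fit of all libraries.

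Interferon-stimulated, inflammatory and immediate early genes rose in clone 2. All but 2 of the 41 measured interferon list members rose, with a median log2 fold change of 2.92, and none fell, also over the list alone. IFI27 reached 1020 ± 56 CPM, and IFI44 rose by 8.82 (SE 0.36). The camera adjusted p was 1.21e-78, and adjusted p = 0.0607 with an estimated correlation. In the NF-kB list 16 of 18 members rose and none fell, also over the list alone, with BIRC3 at 4.31 (SE 0.15) and the chemokine CCL2 at 3.85 (SE 0.57), and adjusted p = 0.0308 with an estimated correlation. MHC class I had 13 of 17 members higher and 2 lower, also over the list alone. Its activator NLRC5 rose by 2.31 (SE 0.22), with adjusted p = 0.117 with an estimated correlation. Of 19 immediate early genes 16 rose and none fell (18 adjusted over the list alone), with adjusted p = 0.0308 with an estimated correlation. FOS went from 10.9 ± 3.8 to 159 ± 6.2 CPM, FOSB rose by 4.82 (SE 0.20) and DUSP1 by 3.12 (SE 0.17). The leukocyte transcripts named for clone 4 summed to 3.64 and 3.38 CPM, by library total, here, against 1.53 to 3.00 in parental cells, and ITGAM had 47 and 59 counts.

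The IL-6/JAK/STAT3 list rose in clone 2, with 20 of 36 members higher and 3 lower, also over the list alone, and kept its call with an estimated correlation (adjusted p = 0.0308). STAT3 rose from 91.8 ± 4.1 to 142 ± 1.3 CPM, a log2 fold change of 0.63 (SE 0.094), LIF rose by 4.27 (SE 0.30) and SOCS3 by 1.16 (SE 0.20). IL6ST was at -0.06 and not called, and IL6 had 6 counts over both libraries. FOS and JUNB of this list are also immediate early genes, and IRF9 and CXCL10 are interferon-stimulated genes. The call is therefore not independent of those rises, and the list was not tested without these members.

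**Figure D2:**
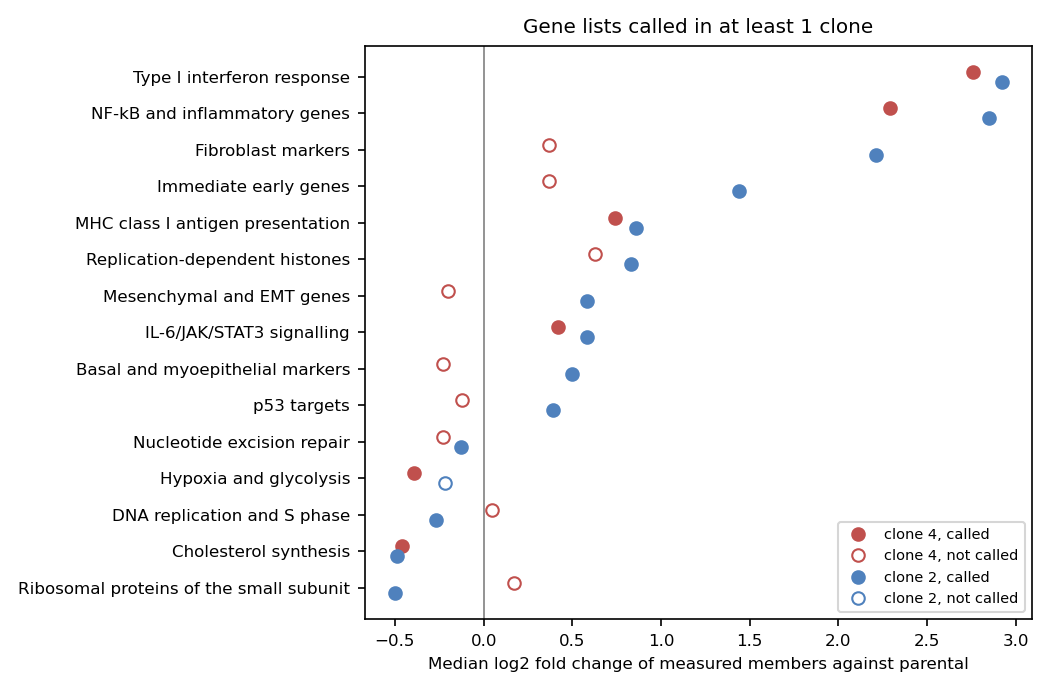
Median log2 fold change against parental (x axis) of the measured members of the 15 lists (y axis) called in at least 1 clone, with filled points where the list was called by camera at a preset correlation and open points where it was not. The interferon and NF-kB lists lay highest in both clones, at 2.76 and 2.29 in clone 4 and at 2.92 and 2.85 in clone 2.

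Genes of other cell states also rose in clone 2. The mesenchymal list had 9 of 21 members higher and 4 lower, also over the list alone. TNC, the matrix protein tenascin C, went from 0.336 ± 0.10 to 28.7 ± 0.41 CPM, and VIM from 0.999 ± 0.14 to 4.06 ± 0.19 CPM. CDH1 was at 0.15 and not called. The list had camera adjusted p = 0.000139, and adjusted p = 0.203 with an estimated correlation. Of 13 basal markers 8 rose and none fell, also over the list alone, including KRT15 at 1.57 (SE 0.24) and KRT5 with 30 counts against 1 (ratio 44.6, 95% interval 7.41 to 1820), with adjusted p = 0.266 with an estimated correlation. Among 7 measured fibroblast markers 6 rose, also over the list alone, with adjusted p = 0.0308 with an estimated correlation. COL3A1, a fibrillar collagen, had 2708 counts in clone 2 and 1 in parental cells, a ratio of 4030 (95% interval 722 to 159000), while COL1A2 stayed at 0.0909 and 0.255 CPM by library total. Of 23 p53 targets 11 rose and 3 fell (12 and 4 adjusted over the list alone), including BTG2 at 2.53 (SE 0.12) and TP53I3 at 1.02 (SE 0.091), with adjusted p = 0.103 with an estimated correlation.

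Ribosomal and sterol genes were mostly lower in clone 2, and smaller parts of the replication and excision repair lists were. Of 18 small-subunit ribosomal proteins 16 fell and none rose (17 adjusted over the list alone), with RPSA at -0.92 (SE 0.10) and adjusted p = 0.555 with an estimated correlation. In cholesterol synthesis 17 of 23 members fell and 1 rose, also over the list alone, led by NSDHL at -2.16 (SE 0.16), with adjusted p = 0.451 with an estimated correlation. The DNA replication list had 12 of 35 members lower and 1 higher (10 and 1 adjusted over the list alone). Its adjusted p of 0.0498 became 0.215 without parental replicate 3 and 0.0512 without clone 2 replicate 2, and was 0.783 with an estimated correlation. Nucleotide excision repair had 8 of 20 members lower and 1 higher, also over the list alone, with CETN2 at -1.52 (SE 0.13). Its adjusted p of 0.0441 lay between 0.0521 and 0.0593 without parental replicate 1, clone 2 replicate 1 or either clone 4 library, and was 0.304 with an estimated correlation. Histone genes rose in 6 of 10 cases, also over the list alone, led by HIST2H2BE at 2.01 (SE 0.18). That adjusted p of 0.033 became 0.0567 without clone 2 replicate 1 and 0.07 without clone 4 replicate 1, and was 0.451 with an estimated correlation.

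Homologous recombination was not called in clone 2, with 3 of 30 members higher and 9 lower, also over the list alone (camera adjusted p = 0.365). BLM fell by 1.04 on the log2 scale (SE 0.16), RBBP8 rose by 1.05 (SE 0.14), and BRCA2 was at -0.04 and not called. BRCA1 fell by 0.42 (SE 0.13), a call lost without either clone 2 library (adjusted p = 0.0751 and 0.134). ESR1, the estrogen receptor gene, fell from 176 ± 6.7 to 91.7 ± 4.7 CPM, a log2 fold change of -0.94 (SE 0.10), and PGR fell by 0.98 (SE 0.21). Of 30 members of the estrogen receptor list 9 rose and 11 fell (11 and 12 adjusted over the list alone, camera adjusted p = 0.510). AREG, a growth factor, rose by 3.93 (SE 0.31) and PDZK1 by 3.77 (SE 0.19).

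In all, edgeR called 7443 genes in clone 2 against parental, 3805 higher and 3638 lower, with 1737 up and 703 down at least 2-fold. The count was 4631 without clone 2 replicate 1 and 4291 without clone 2 replicate 2, and a test against a fold of 1.5 called 2177. Called here and between the clones but not in clone 4 were COL3A1, FOSB, HPSE2 and TRIM29, higher, and C3orf58, ACOX2, OLMALINC and SULT2B1, lower by log2 fold changes of -2.12, -2.05, -1.89 and -1.74. HPSE2 and TRIM29 rose by 3.88 (SE 0.21) and 3.66 (SE 0.18).

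Among genes that rose in both clones, interferon-stimulated genes were prominent. IFI44L had 0 counts in parental cells and was at least 48.7-fold higher in clone 4 and at least 177-fold higher in clone 2. RSAD2, an antiviral protein, rose by log2 fold changes of 6.04 (SE 0.43) and 6.78 (SE 0.40), and IGFBP3, which binds insulin-like growth factors, by 6.44 (SE 0.25) and 5.80 (SE 0.26). GLYATL3 rose by 5.65 and 5.87, and ARSJ had 287 counts in clone 4 and 165 in clone 2 against 2 in parental cells. PMP22, a myelin protein, fell from 91.2 ± 9.3 CPM to 0.263 ± 0.017 in clone 4 and 0.348 ± 0.0090 in clone 2. ANGPT1, BCHE and NR2F1 had log2 fold changes of -7.48, -5.58 and -5.28 in clone 4, and of -5.83, -5.75 and -5.20 in clone 2. The cancer-testis gene MAGEA6, whose reads may be shared with its copies, had 2035 counts in parental cells, 1 in clone 4 and 0 in clone 2, and its neighbour CSAG1 had log2 fold changes of -7.24 and -6.08. DSCAM-AS1, a non-coding RNA antisense to DSCAM, had 624 counts in parental cells and 1 in clone 4 (ratio 388, 95% interval 69.5 to 15400).

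In the same direction, 3789 genes were called in both clones, 1918 higher and 1871 lower, and 452 were called in opposite directions. Without clone 2 replicate 2 the shared count was 2437, and a test against a fold of 1.5 in both gave 1034. Independent lists of these sizes would share 840 higher and 813 lower genes. Unchanged groups simulated against shared parental libraries shared 0.25 genes on average over 20 simulations. These simulations held no real differences, so hardly any gene could be called in them. They do not measure how much overlap shared parental libraries add where real differences exist. Log2 fold changes of the clones had a correlation across genes, which are not independent replicates, of 0.66 and a covariance of 0.629, against 0.39 and 0.0229 in the simulations. The sign was the same for 67.6% of genes, against 63% in the simulations and 64.1% in the highest of them. The 3 parental libraries could not be split into sets of at least 2 each, so part of the shared calls may come from sharing them. The covariance lay 0.606 above the simulated mean, and the simulated groups, which shared these libraries too, reached at most 0.0254. At the spread simulated, these values argue against sharing as the source of most of the covariance. The mean of both clones against parental gave 7847 called genes, 3839 higher and 4008 lower, and 3747 when the 4 resistant libraries formed 1 group.

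The comparison of clone 2 with clone 4 tests whether their differences from parental cells differ. Names of the clone 2 libraries are built otherwise than those of parental cells and clone 4. If the clone 2 libraries were prepared apart, that difference could not be told apart from the clone, here or against parental cells. RB1 was higher in clone 2 by a log2 fold change of 7.18 (SE 0.27). COL3A1, NDN and RCBTB1 had 0 counts in clone 4 and were at least 836-fold, 93.2-fold and 77.4-fold higher in clone 2. LDHB, a lactate dehydrogenase subunit, was at 70.2 ± 5.1 CPM in parental cells, 51.1 ± 2.5 in clone 2 and 0.236 ± 0.14 in clone 4. MAGEA1 was higher in clone 2 by 6.54 (SE 0.34). PKIA, an inhibitor of protein kinase A, had 6209 counts in parental cells, 152 in clone 4 and 0 in clone 2. GFRA1, a receptor for glial-derived neurotrophic factor, was lower in clone 2 with a log2 fold change of -5.67 (SE 0.46), CRABP1 with -2.37, WNT5A with -2.27 and STC1 with -2.25. WNT5A, a secreted Wnt ligand, was at 0.793 ± 0.045 CPM in parental cells, 74.3 ± 3.9 in clone 4 and 15.4 ± 0.87 in clone 2.

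By list, 6 were higher and 3 lower in clone 2 than in clone 4 at the preset correlation, and none was called with an estimated correlation, where the lowest adjusted p was 0.0956. Immediate early genes were higher in 12 of 19 cases, with FOS at 5.11 (SE 0.30), and the mesenchymal list in 13 of 21 with 1 lower, including CALD1 at 2.98 (SE 0.21). Basal markers were higher in 8 of 13 cases, fibroblast markers in 6 of 7 and p53 targets in 10 of 23, with the p53-induced kinase PLK2 at 2.31 (SE 0.20). Each of these counts was the same adjusted over the list alone. Of 11 ABC transporters 6 were higher and 1 lower, also over the list alone, led by ABCC3 at 1.74 (SE 0.24), a list call lost without clone 4 replicate 1 (adjusted p = 0.0996). Small-subunit ribosomal proteins were lower in 15 of 18 cases (16 over the list alone), with FAU at -1.08 (SE 0.14). Mitochondrially encoded genes were lower in 10 of 13 (12 over the list alone), with MT-ND3 at -1.09 (SE 0.15), beside mitochondrial shares of all counts of 12.6% and 15.6% in clone 4 and 11.5% and 11.3% in clone 2. DNA replication genes were lower in 14 of 35 and higher in 2, also over the list alone, with PCNA at -0.85 (SE 0.12), a list call lost without clone 4 replicate 1 (adjusted p = 0.0622). Interferon, NF-kB and MHC class I lists were not called between the clones (camera adjusted p = 0.752, 0.995 and 0.803), but the interferon list was called without clone 4 replicate 1 (adjusted p = 0.0194), with adjusted p = 0.996 with an estimated correlation in the fit of all libraries.

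In all, 6396 genes were called between the clones, 3422 higher and 2974 lower in clone 2. The count was 3621 without clone 2 replicate 1, 3289 without clone 2 replicate 2 and 1393 in a test against a fold of 1.5.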

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

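The tests of chromosome segment, read depth, cell mixture and single libraries for RB1, interferon and fibroblast genes were set before their results were seen, except the COL1A2 test, the ratio over all leukocyte list members and the count of regroupings, which were chosen afterwards.

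Each result in this paragraph and the next was picked out because it differed between the clones, genes by the edgeR test and lists by camera at the preset correlation. This held for 6396 genes and for 9 lists, none of which was called with an estimated correlation (lowest adjusted p = 0.0956), with median log2 fold changes in clone 2 against clone 4 of 2.51 for fibroblast, 1.07 for immediate early, 0.97 for basal, 0.56 for mesenchymal, 0.41 for p53, 0.36 for ABC transporter, -0.25 for DNA replication, -0.52 for mitochondrial and -0.72 for ribosomal genes. Among cell cycle genes the log2 differences were 7.18 for RB1, 1.26 for CDK6, 1.16 for CDKN1A, 0.86 for CCND1, 0.59 for CCNE1, -0.56 for E2F1 and -0.67 for CCNE2. BRCA2 differed by 1.16, BRCA1 by -0.44, ESR1 by -0.89, STAT3 by 0.47, SOCS3 by -1.17, IL6ST by -0.53, CDH1 by 0.61 and VIM by 2.16.

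Of the genes that moved alike against parental cells, IFI44L still differed by 1.88, ANGPT1 by 1.65, IFI27 by 1.29, IFI44 by 0.78, RSAD2 by 0.74, IGFBP3 by -0.63 and ARSJ by -0.92 on the log2 scale, and MAGEA12 by a ratio of 7.87 (95% interval 1.87 to 70.2). Higher in clone 2 were LDHB by 7.76, MAGEA1 by 6.54, FOSB by 4.67, SCARA3 by 4.05, L1CAM by 3.78, HPSE2 by 3.54, TRIM29 by 3.09, EYA2 by 2.89 and PNPLA4 by 2.46. COL3A1, NDN and RCBTB1 were higher there by at least 836-fold, 93.2-fold and 77.4-fold, and PKIA was at least 54.7-fold higher in clone 4. Lower in clone 2 were GFRA1 at -5.67, CITED1 at -2.61, CRABP1 at -2.37, WNT5A at -2.27, STC1 at -2.25, PIP at -2.23, ACOX2 at -2.16, C3orf58 at -1.97, ARHGAP15 at -1.95, SULT2B1 at -1.80, C4orf48 at -1.71 and OLMALINC at -1.58. A further 77 of 105 list members named by the rule differed between the clones, against 36.5% of all genes tested. These members were named because a contrast, this one among them, called them, so their share was raised in advance.

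For the mean of both clones against parental, the 7 libraries were regrouped into groups of 3, 2 and 2. Of 100 regroupings, only the real 1 gave as many as 7847 called genes. The highest other count was 2833, from a split that kept the parental libraries together and mixed the clones. Each other regrouping put libraries of different lines in the same group, which widens the spread within groups. The real grouping was thus favoured in advance, and the counts show only that libraries of a line resemble each other.

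RB1 was nearly absent in clone 4, with 2 and 3 counts in its libraries. Too few reads do not account for it, since the 200 genes nearest to RB1 in parental level had a median ratio of 0.918 in clone 4. Loss of a chromosome segment stays open. RB1 stood in a run of 2 neighbouring expressed genes below 0.1 of the parental level, short of the 3 set as the minimum. A run as long stood anywhere in the genome in 36.9% of shuffled gene orders. That share does not tell how often RB1 itself would fall in such a run. The other member of the RB1 run, LPAR6, lies within RB1, so both may reflect a single lesion or shared reads. The next genes on either side, ITM2B and RCBTB2, had ratios of 0.616 and 0.145, the latter on 5 and 0 counts. Beyond RCBTB2, FNDC3A and CDADC1 had 0.473 and 0.971, and CAB39L after them 0.0958, so low and kept genes alternate there. The genes listed here end at CAB39L and leave out any losses further along the chromosome. RCBTB1, with 893 counts in parental cells and 0 in clone 4, is not among them.

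The type I interferon list rose in both clones. The tables argue against leukocytes mixed into the cultures, because 6 leukocyte transcripts together reached at most 0.00435 of the summed rise of MX1, IFIT1 and ISG15 in a resistant library, below the 0.01 set in advance. All 16 members of the leukocyte list, ITGAM and CD68 among them, reached at most 0.018 of it, above that bound but below the 0.1 set in advance as the least that leukocytes would bring. PTPRC, the pan-leukocyte antigen, had at most 1 count in a library. Nor did 1 library per clone carry it: the lowest list median in a resistant library was 2.49 on the log2 scale against the parental mean. A change in the resistant lines themselves remains as a hypothesis, and the trigger of the interferon genes was not tested.

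Fibroblast markers rose in clone 2. Mixed-in fibroblasts are excluded as the source of COL3A1, since such cells would bring their other abundant transcripts. COL1A2 reached at most 0.00267 of the COL3A1 level in clone 2, and by library total (as for all CPM in this paragraph), against 110 and 95.6 CPM of COL3A1 stood 3.00 and 3.83 CPM of LUM and 0.818 and 1.08 CPM of DCN, with 0 counts of FAP and POSTN. The test set in advance did not decide by itself: COL1A1 reached 1.36 of the COL3A1 level, above the 0.1 that would have spoken against them, and it rose from 38.5 to 40.3 CPM in parental cells to 139 and 131 CPM, as mixed-in fibroblasts would require, but COL1A2 did not rise as that test also required. COL1A1 rose to 70.5 and 99.1 CPM in clone 4 too, where COL3A1 had 0 counts. An earlier version of this test checked only a part of its written prediction and came out in favour of fibroblasts; it was corrected after that result was seen. Expression of COL3A1 by the clone 2 cells themselves may account for it and was not tested.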

How the results depend on the processing

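The alternatives covered scaling, filter, tool, libraries left out, replicate block, groups fitted and the test against a fold of 1.5. Together they gave 3435 alternative values for the 246 values of named genes. Of these, 3323 stayed on the same side of the threshold, 108 lost the call and 4 gained it. No value called in the main analysis or in the alternative turned its direction. Turns of values called in neither were not counted. A test against a fold of 1.5 accounts for 53 of the lost calls, as its construction asks for more than a difference from 0. With RLE scaling no named gene or list changed its call, but the balance of directions moved: 3632 higher and 3828 lower in clone 2, and 3210 and 3186 between the clones. DESeq2 gave 2736 and 3441, and 2415 and 2640, so which direction held more genes depends on the scaling and tool. Of the 1152 alternative values of 96 list results, 42 lost and 59 gained a call. None called in the main analysis or in the alternative turned, and turns of other list values were likewise not counted.

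A test against a fold of 1.5 called 2382 genes in clone 4, 2177 in clone 2, 2055 in the mean of both, 1393 between the clones and 1034 in both clones alike. Taking the 4 resistant libraries as 1 group called 3747, with the difference between the clones then counted as spread. For the lists, an estimated correlation left 1 call in clone 4, 4 in clone 2 and 0 between the clones, fry gave 12 in clone 4 and 14 between the clones, and no filter gave 12 in clone 4. The cause of these list differences was not tested.

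Leaving out each library in turn gave 5355 to 8060 genes in clone 4, 4291 to 7988 in clone 2, 6183 to 8032 in the mean, 3289 to 7348 between the clones and 2437 to 4068 in both clones alike. The called lists ranged from 6 to 8 in clone 4, 12 to 17 in clone 2 and 8 to 11 between the clones. Where a clone was left with 1 library, that library was assumed to vary like the other groups.

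With the replicate block the counts were 8551 in clone 4, 8194 in clone 2, 8413 in the mean, 7831 between the clones and 4394 in both clones alike, with 8, 16 and 12 lists called. Among list results 9 gained a call, such as the stress response in clone 4 and clone 2 (adjusted p = 2.99e-08 and 1.67e-09), and 2 lost it, and E2F1 in clone 2 gained one (adjusted p = 0.0378). Parental replicate 3 is the only library of its number, so the block also takes it out of the contrasts, and most of these list changes also appeared without it. The clone 2 libraries enter as replicates 1 and 2, though their names carry 4 and 6. Same-numbered libraries of parental cells and clone 4 deviated together at correlations of 0.19 and 0.11, those of parental cells and clone 2 at 0.01 and -0.01, and those of the clones at -0.08 in both cases, and 2 pairs are too few to show that the numbers pair the samples. Depth limits genes near the floor: 3 counts correspond to 0.171 to 0.273 CPM per library.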

Other observations

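The tests on chromosomes and on nucleotide excision repair members were chosen after the values they concern had been seen.

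The unfolded protein and integrated stress response list was not called against parental cells in the fit of all libraries. Its medians were -0.34 in clone 4 and -0.65 in clone 2 (camera adjusted p = 0.225 and 0.114). Of its 25 members 6 were lower and 1 higher in clone 4, and 7 were lower and 3 higher in clone 2. Without parental replicate 3 the list was called lower in both clones, with medians of -0.58 and -0.91 (adjusted p = 9.17e-08 and 1.16e-08). These values assume the preset correlation of 0.01, whereas the correlation estimated in the fit of all libraries was 0.923 and 0.920, with adjusted p = 0.987 and 0.783. In clone 2 it was also called with no filter beyond 1 count (-0.68, adjusted p = 0.0292). Breast stem cell genes in clone 2 had 7 of 17 members higher and 2 lower, with adjusted p = 0.0624 that became 0.00528 without the same library and 0.0438 without clone 2 replicate 2, and was 0.367 with an estimated correlation. Of all genes tested, 44.4% were called in clone 4 and 42.5% in clone 2 against parental, about equally in both directions. Mitotic genes had 8 of 35 members lower and 2 higher in clone 4, and 10 lower and 1 higher in clone 2 (camera adjusted p = 0.227 and 0.075). They were called lower without parental replicate 2 in both clones (adjusted p = 0.0227 and 0.00477), and in clone 2 also without parental replicate 1 (0.0395) or clone 2 replicate 2 (0.0472), all at the preset correlation, against adjusted p = 0.987 and 0.783 with an estimated correlation in the fit of all libraries.

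The median over all genes of a chromosome lay away from 0 for several chromosomes. Genes of chromosome 13, which carries RB1 and BRCA2, had a median log2 fold change of -1.15 in clone 4, with 94.2% of 243 genes below 0, and -0.53 in clone 2. Chromosome 14 was at 0.49 and 0.46, chromosome 15 at -0.49 and -0.22, and chromosome 9 at -0.36 and -0.12, where parts of the chromosome were not examined. BRCA2 in clone 4, at -1.20, lay near the median of its chromosome. CUL4A, on the same chromosome, was at -1.68 in clone 4. RB1 in clone 2 fell further than the chromosome's median of -0.53 there. Fewer copies of the whole of chromosome 13 in clone 4 are a candidate explanation: in 5 equal parts of its genes in order the medians were -0.96 or lower, and the last was at -1.67. GC content or transcript length do not account for it, since genes of other chromosomes matched on both and on level had a median no lower than -0.17 in 1000 draws. Copy number itself was not measured in these data, and RB1 at -8.13 lies far below such a shift.

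Members of the nucleotide excision repair list on chromosomes 13 and 9 (CUL4A, ERCC5, XPA and RAD23B) may carry part of that list's fall in clone 2. The other 16 members had a median of -0.02 and an unadjusted camera p of 0.091, against 0.018 for all 20. However, 5 of the 8 members called lower lay on other chromosomes, CETN2 among them, so the 2 readings cannot be told apart with so few genes. The condition on members elsewhere was added after the other values were seen, and without it the test would have favoured these chromosomes.

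Runs of neighbouring genes below 0.1 of the parental level also stood elsewhere. In clone 2, 6 genes in a row on chromosome 8 fell this far, among them PKIA, ZC2HC1A and IL7. On chromosome X a run of 7 genes in clone 4 and of 4 in clone 2 held MAGEA3, CSAG1, MAGEA12 and MAGEA6. No cause was tested for these runs, and reads of the MAGEA copies were not separated.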
